A study of Homo sapiens with 12 samples.

How the data were processed

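Gene expression was measured on 12 one-colour Affymetrix arrays from HEL cells, a human erythroleukaemia line that carries an activating JAK2 mutation on all copies, per the labels. Cells received 1 of 2 lentiviral short hairpin RNAs against JAK2 (Jak2-9 and Jak2-10) or 1 of 2 controls (GFP, named both a vector and a hairpin control in the labels, and a luciferase hairpin, Luc), with 3 arrays in each of the 4 groups. RNA was isolated with Trizol, and 20 ng of total RNA per sample was amplified linearly with a NuGEN biotin kit, per the labels' protocols. The labels number the replicates but do not call them separate cultures, so p-values measure the spread between these arrays, which may be technical.

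The authors deposited 1 table of linear-scale intensity values per probe set and array, processed with RMA per the submitters' processing notes; the RMA software version is not given in the sources used here. RMA subtracts background, quantile normalizes the arrays and summarises probes, which makes the arrays' distributions alike and compresses fold changes of dim probe sets. The design had assumed log2 values, but the deposited table held linear intensity (11.2 to 36233.5), so log2 was taken before any test and no pseudocount was added. Median intensity lay between 44.9 and 49.1 on the 12 arrays. Detection calls were not used here, so values of dim probe sets may be background. Sequencing depth has no counterpart on arrays, and the number of arrays limits the precision.

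Of 22930 probe sets in the table, 524 were control probe sets and were left out of all gene tests, including 98 that the annotation pairs with 1 gene symbol. Among the others, 19415 had 1 gene symbol in the platform annotation, 125 had several and were not named, and 2866 were not named here. For 19290 of the 19415 the Entrez identifier was matched to the RefSeq gene table, and no symbol changed. Each of 11940 genes was represented by its probe set with the highest mean log2 intensity over the 12 arrays; 4507 genes had 2 or more probe sets. Genes of fixed lists without a probe set of their own name were not analysed here. No coordinates are given, since the deposited table names no genome build.

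A linear model with 4 group means was fitted to all 12 arrays (limma 3.58.1 in R 4.3.3, lmFit and eBayes), so that all groups shared 1 estimate of the spread per gene. Adjusted p-values are Benjamini-Hochberg values over the 11940 genes, with a threshold of 0.05. Contrasts were the mean of both JAK2 hairpin groups minus the mean of both control groups, each hairpin minus the mean of the controls, Jak2-10 minus Jak2-9, and Luc minus GFP. A gene was also counted when it passed with the same sign in all 4 comparisons of 1 hairpin with 1 control. The 20 gene lists were written before the data were examined and tested with limma's camera at a preset correlation of 0.01, adjusted over the 20 lists. Single values were compared with exact two-sided permutation tests in Python 3.11.15 with scipy 1.17.1.

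The genes named were set by a rule written before the data were examined. They are JAK2, up to 12 genes with the largest fall and up to 12 with the largest rise among those called in all 4 comparisons, and members of lists. The members are up to 4 that passed with the largest change, or the 2 with the lowest p where none passed. The rule took these for each list called in a comparison, and for the JAK-STAT target, JAK-STAT component, erythroid, megakaryocyte and cell cycle lists whether called or not. It also took the 5 largest rises and falls past the threshold in Jak2-10 minus Jak2-9 and the 3 and 3 in Luc minus GFP. Genes outside it are stated to have been chosen after their values were seen.

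The fit was tested on simulated data with the real means and spreads of the 11940 genes in 5 runs of 200 changed genes. For knockdown versus control it called 29.1% of genes changed by 0.3 on the log2 scale, 84.2% of those changed by 0.5, and 100% of those changed by 1 or 2. Calls in all 4 comparisons recovered 20.2% of genes changed by 0.5 and 99.1% of those changed by 1. Unchanged genes made up 6.17% of the calls in knockdown versus control. A list shifted by 0.3 was called in 5 of 5 runs, and no other list was called. The simulated genes varied independently of each other, so this cannot show how often lists of correlated genes are called falsely. On the real arrays, other splits of 6 against 6 called up to 5 lists.

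Alternatives were a replicate block, median centring, quantile normalization, leaving out the dimmest 30% of genes, the mean of all probe sets of a gene, an intensity trend in the prior variance, and array weights. Others were a minimum fold change of 2, each probe set on its own, fits limited to the arrays compared, single controls, a fit without hairpin terms, the hairpin as a random block, and leaving out each array in turn. Camera with an estimated correlation and fry were alternatives for lists. Leaving out Jak2-9 replicate 1 and Jak2-10 replicate 3 together was added after seeing the data.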

Results

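Expression profiles were obtained from HEL cells in 4 groups of 3 arrays: a GFP control, a luciferase hairpin control (Luc), and the JAK2 hairpins Jak2-9 and Jak2-10. JAK2 is the tyrosine kinase that carries signals from cytokine receptors to STAT transcription factors, and HEL cells carry an activating mutation of it. Correlation between arrays of 1 group lay between 0.997 and 0.998 for both controls, between 0.995 and 0.998 for Jak2-10, and between 0.986 and 0.997 for Jak2-9. Jak2-9 replicate 1 stood apart: 253 genes differed from the mean of the other 2 Jak2-9 arrays by more than 2-fold, against 0 or 1 on each control array.

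The JAK2 transcript, the target of both hairpins, was examined first. At the brighter of its 2 probe sets the mean intensity was 1469 ± 151 in GFP cells, 1506 ± 84.6 in Luc cells, 899.5 ± 217 with Jak2-9 and 998 ± 103 with Jak2-10 (SD, n = 3 each). The mean of both hairpins was 63.1% of control, a log2 fold change of -0.67 with a standard error of 0.11 (limma, adjusted p = 0.00400). JAK2 was at 59.3% of control with Jak2-9 (95% interval 48.5% to 72.5%, adjusted p = 0.00768). With Jak2-10 it was at 67.0% (54.8% to 81.9%), which missed the threshold over all genes (adjusted p = 0.0824). All 6 knockdown arrays lay below all 6 control arrays at both probe sets. An exact two-sided permutation test of each hairpin against the 6 control arrays gave p = 0.0238 at each probe set, the smallest value that 84 arrangements can give, and 0.0238 after adjustment over the 4 tests. The dimmer probe set gave a log2 fold change of -0.73 ± 0.17 (SE), or 60.1% of control. The size of that fall with Jak2-9 leaned on replicate 1, at 7.11 on the log2 scale against 8.35 and 8.40 on the other Jak2-9 arrays. The control means there were 8.80 (GFP) and 8.78 (Luc). At the brighter probe set Jak2-9 replicate 1 also held the lowest JAK2 value of the 12 arrays, 9.37 on the log2 scale, against 9.89 and 10.09 on the other Jak2-9 arrays. Luc and GFP differed by 0.04 ± 0.16 (SE) on the log2 scale.

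**Figure D1:**
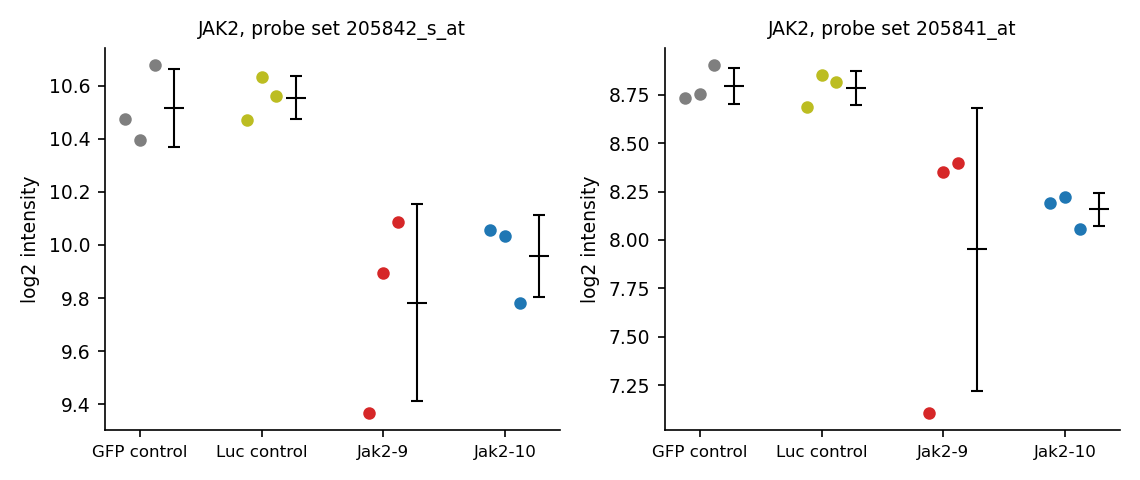
JAK2 log2 intensity (y axis) on each array of the 4 groups (x axis) at its 2 probe sets; points are arrays, and the black bars give the mean and SD of 3 arrays. The knockdown arrays lie below the control arrays at both probe sets, with means of 9.78 (Jak2-9) and 9.96 (Jak2-10) against 10.52 (GFP) and 10.56 (Luc) at the brighter probe set.

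The comparison of both JAK2 hairpins with both controls asks which transcripts change when JAK2 is reduced in cells with mutant JAK2. Of 11940 genes 166 fell and 52 rose (limma, adjusted p under 0.05), of which 23 and 1 changed at least 2-fold. The balance of directions depended on scaling and weighting: 150 fell and 135 rose with each array centred on its median, 271 fell and 269 rose with array weights, and 683 were lower and 1259 higher at unadjusted p under 0.05. With GFP alone as control 36 fell and 5 rose, and with Luc alone 106 fell and 12 rose. The genes that passed in all 4 hairpin-control comparisons all fell, 15 in number; with array weights 57 fell and 6 rose. POLQ, the DNA polymerase theta of end joining repair, was at 18.4% of control (log2 fold change -2.44 ± 0.12, SE, adjusted p = 1.19e-07). LINC00680, a long noncoding RNA, was at 18.3% (-2.45 ± 0.18, adjusted p = 5.49e-06). RFX3, a transcription factor of ciliated cells, was at 27.5% (-1.86 ± 0.13), and CTTNBP2NL had a log2 fold change of -1.74 ± 0.15. GABBR1, a subunit of the GABA-B receptor, was at 31.9% (-1.65 ± 0.17), and CEP152, a scaffold protein of centriole duplication, at 35.7% (-1.49 ± 0.09). SNHG3, a host transcript of small nucleolar RNAs, was at 38.4% (-1.38 ± 0.12). SLC35E1, ZNF721 and MPDZ were at 48.0%, 49.3% and 49.5% of control. ANKRD36B (32.5%) and AGAP4 (52.3%) belong to families of near-identical copies, so their values are uncertain as to the copy. These 12 named genes had adjusted p-values of 7.86e-05 or lower. The size of some falls depended on the probe set: with the mean of all probe sets of a gene, RFX3 was at -0.98 and SLC35E1 at -0.27 (adjusted p = 0.0341). The remaining 3 of the 15 were RSRP1 (-0.82), CROCCP2 (-0.91) and DBF4B (-0.79), named here after their values were seen.

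Of the 166 fallen genes, 133 had all 6 knockdown arrays below all 6 control arrays, as did 33 of the 52 risen genes in the other direction. Of the fallen genes 74 had more than 1 probe set, with a median of -0.66 at the brightest and -0.36 at the others, which lay above 0 for 12 genes. For genes not selected on these arrays, chance separates the 6 knockdown from the 6 control arrays in 0.216%, and 2.71% of all genes showed it. The fallen and risen genes were selected on these same arrays, so their own separation adds no evidence. Among other genes chosen after their values were seen, the long noncoding RNA NEAT1 (-1.01), the cyclin CCNL1 (-1.09), the kinase CLK1 (-0.49) and the splicing factor SRSF11 (-0.60) fell. The largest rises were those of ZNF236 (1.95 ± 0.26, SE), the growth factor PTN (0.89 ± 0.11) and the galactokinase GALK1 (0.82 ± 0.10), also named after seeing their values. The human Alu control probe set, which reads a repeat found in many introns and untranslated regions, moved with the fallen genes. It was 14.61 ± 0.07 (SD, n = 6) on the log2 scale in controls and 14.06 ± 0.10 in knockdown arrays, with no overlap (exact two-sided permutation p = 0.00216, the smallest that 924 arrangements can give). Leaving out 1 array moved the count of 218 changed genes beyond 1.5-fold in 3 cases, to 131 without GFP replicate 1, 142 without Luc replicate 2 and 352 without Jak2-9 replicate 3. The 15 genes called in all 4 comparisons became 1 without GFP replicate 1, Jak2-10 replicate 1 or Jak2-10 replicate 3, 2 without GFP replicate 2, 3 without Jak2-10 replicate 2, 6 without Luc replicate 3, 7 without Luc replicate 2, 9 without GFP replicate 3 and 38 (36 fell, 2 rose) without Jak2-9 replicate 1, while all 15 were still called in knockdown versus control each time.

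**Figure D2:**
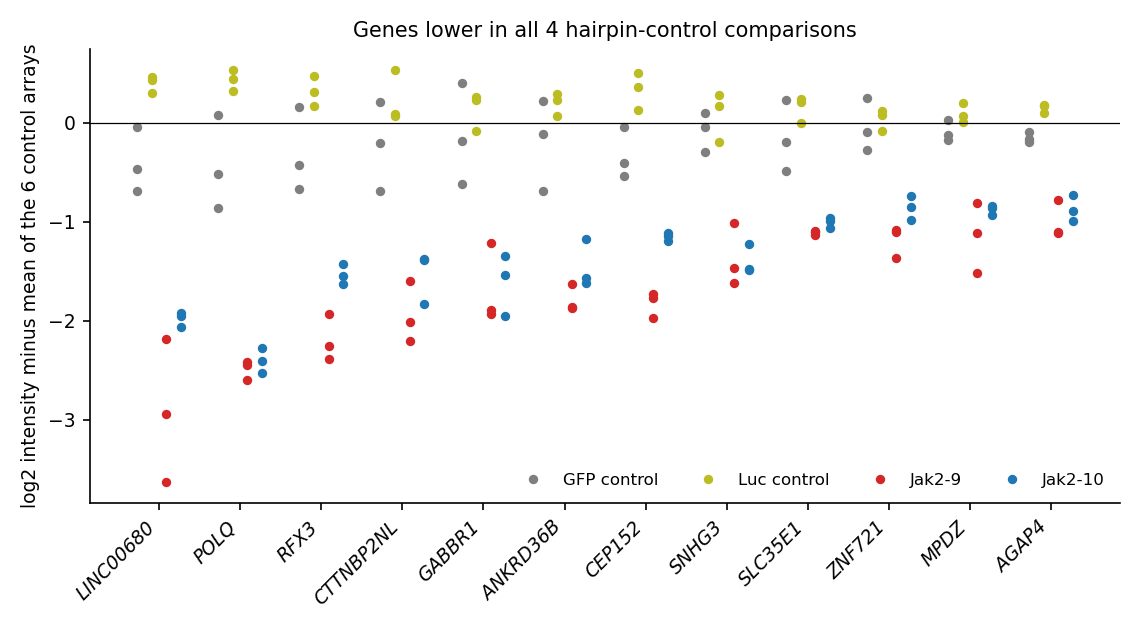
Log2 intensity minus the mean of the 6 control arrays (y axis) for the 12 named genes that fell in all 4 hairpin-control comparisons (x axis); each point is 1 array, coloured by group. Mean falls run from -2.45 (LINC00680) to -0.94 (AGAP4), and every knockdown array lies below every control array.

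**Figure D3:**
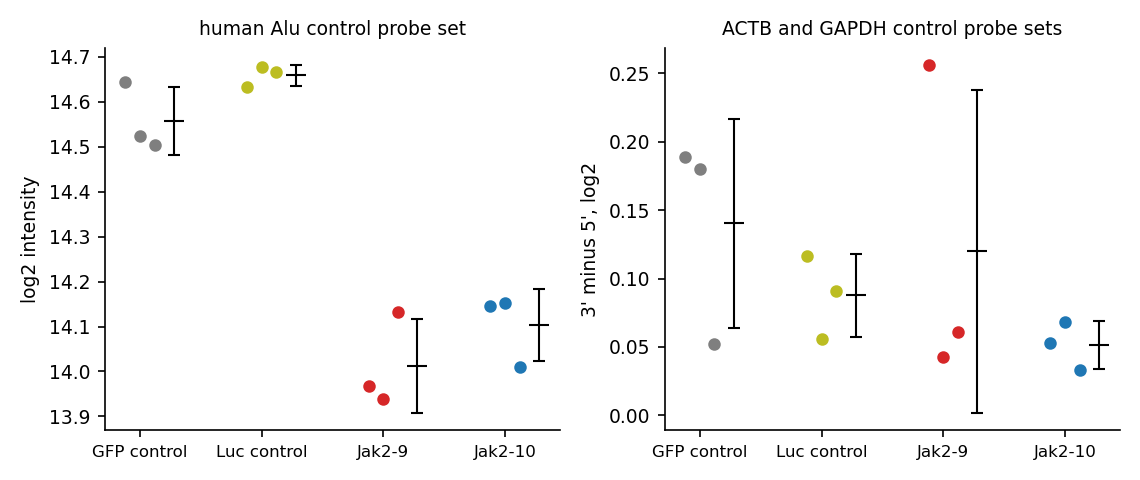
Human Alu control probe set (left, log2 intensity) and the mean 3' minus 5' log2 difference of the ACTB and GAPDH control probe sets (right) on each array by group; black bars give the mean and SD of 3 arrays. The Alu signal is 14.61 in controls and 14.06 in knockdown arrays, while the 3' minus 5' difference is 0.11 and 0.09.

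JAK-STAT target genes did not fall with JAK2. Of 22 measured members 0 passed the threshold (limma; 19 lay above 0 and 3 below), and 1 rose adjusted over the list alone, GFI1B, a transcription factor of erythroid and megakaryocytic cells (0.29 ± 0.07, SE, adjusted p = 0.0527 over all genes). GFI1B passed without GFP replicate 2 (adjusted p = 0.0417), Jak2-9 replicate 1 (0.0388) or Jak2-9 replicate 3 (0.0489), and also with median centring (0.0264) or the mean of all probe sets (0.0297). PIM2, a survival kinase, was at 0.23 ± 0.08 (adjusted p = 0.168). Chosen after their values were seen, CISH, SOCS2, PIM1 and MYC had log2 fold changes of 0.18, 0.03, 0.01 and 0.00, none past the threshold. Among 29 JAK-STAT pathway components 1 rose, IFNAR2, a subunit of the type I interferon receptor (0.31 ± 0.06, adjusted p = 0.0131), and 2 rose and 1 fell adjusted over the list alone. The call of IFNAR2 rested on its brightest probe set: the mean of its probe sets gave 0.08 (adjusted p = 0.497).

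Erythroid genes, 36 measured, held 1 that fell, SLC25A37, the mitochondrial iron importer mitoferrin (67.5% of control, -0.57 ± 0.08, SE, adjusted p = 0.00114), and none that rose; adjusted over the list alone 3 rose and 1 fell. Megakaryocyte and platelet genes held none past the threshold among 35, with CD9 at 0.29 ± 0.07 (adjusted p = 0.0716) and SELP at 0.28 ± 0.07 (adjusted p = 0.0773), and 3 rose adjusted over the list alone; CD9 passed without Jak2-10 replicate 3 (adjusted p = 0.0209), with median centring (0.0257), with quantile normalization (0.0347) and with the mean of all probe sets (0.0453), and SELP with median centring (0.0462). Cell cycle genes did not pass either. Of 38 genes of G1/S and DNA replication, MCM2 (0.27 ± 0.08, adjusted p = 0.125) and TK1 (0.27 ± 0.10, adjusted p = 0.190) had the lowest p, and of 36 of G2/M and mitosis PLK1 (0.31 ± 0.09, adjusted p = 0.118) and AURKB (0.30 ± 0.09, adjusted p = 0.125). Neither cell cycle list had a member past it adjusted over the list alone.

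Of the other lists, cholesterol synthesis had 2 of 21 members that rose, MVD (0.54) and DHCR7 (0.37), glycolysis and hypoxia response 1 of 29, ALDOC (0.48), and FOXO targets 1 of 21 that fell, KLHL24 (-0.64). NF-kB and cytokine genes had NFKBIE rise (0.38) and CXCL2 fall (-0.45) among 25. KLHL24, NFKBIE and CXCL2 lie outside the naming rule and were chosen after their values were seen. Adjusted over the list alone, 3 cholesterol synthesis members, 1 glycolysis member, 1 FOXO target and 1 NF-kB gene rose, and 1 FOXO target and 1 NF-kB gene fell. No member passed over all genes in the ERK output, MYC and ribosome biogenesis, monocyte and granulocyte, lymphoid, haematopoietic transcription factor, interferon-stimulated, p53 target, BCL2 family, amino acid and ER stress, and housekeeping lists. Adjusted over the list alone, 3 amino acid and ER stress genes, 1 lymphoid marker, 1 haematopoietic transcription factor and 1 MYC list gene rose and 1 MYC list gene fell. As a whole, 0 of the 20 lists were called by camera; cholesterol synthesis came closest (median 0.13, adjusted p = 0.0742, adjusted p = 0.939 with an estimated correlation), at an unadjusted p of 0.00371. Camera called 1 list without Luc replicate 2, 2 without Luc replicate 3 or Jak2-9 replicate 1, and 3 without Jak2-10 replicate 3. Camera sets a list against all other genes, and its direction was down for the JAK-STAT component, FOXO, G1/S and p53 lists although their medians were above 0.

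**Figure D4:**
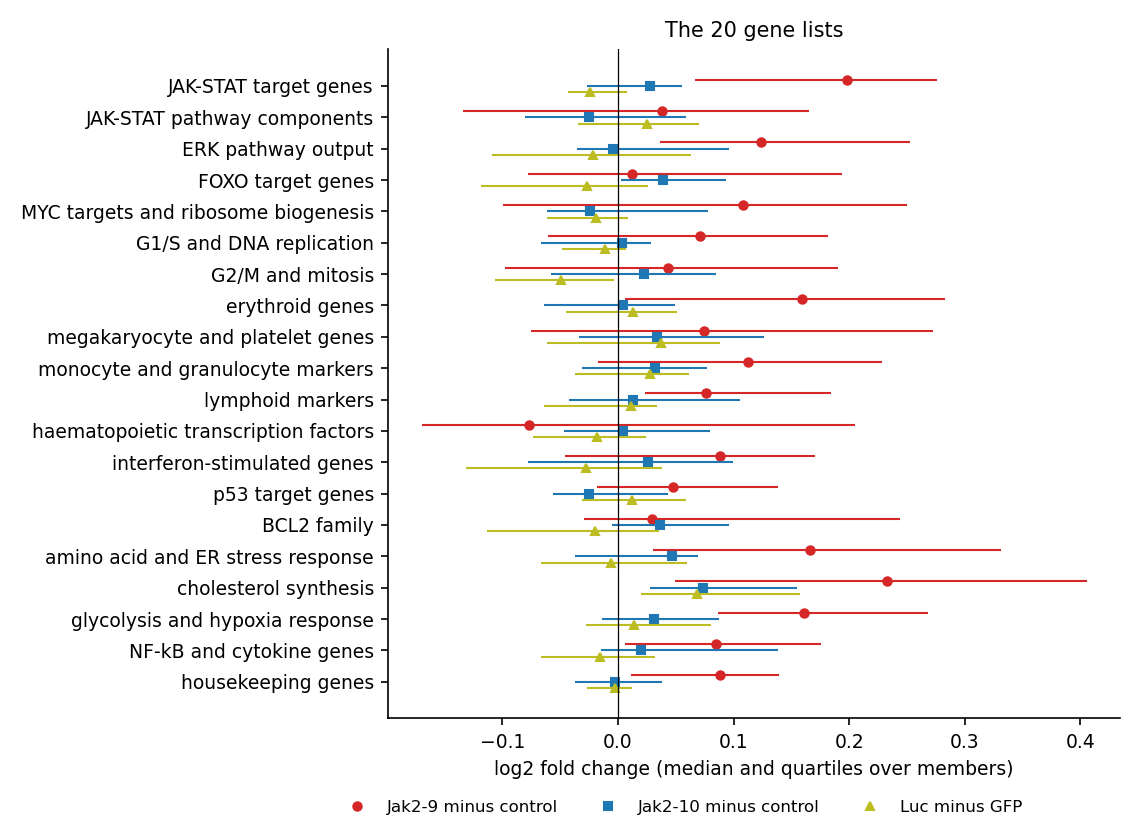
Median log2 fold change (points) and quartiles (lines) over the measured members of each of the 20 gene lists, for Jak2-9 minus control, Jak2-10 minus control and Luc minus GFP. Cholesterol synthesis has medians of 0.23, 0.07 and 0.07, and JAK-STAT target genes of 0.20, 0.03 and -0.02.

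Jak2-9 alone was compared with both controls. It changed 367 genes, 191 up and 176 down (limma). By camera at its preset correlation 3 lists were called, all of them lost with an estimated correlation (adjusted p = 0.872 with an estimated correlation for each) and with fry (0.0624 each). Cholesterol synthesis genes had a median of 0.23 (camera adjusted p = 0.0448; adjusted p = 0.872 with an estimated correlation), with MVD, which makes isopentenyl diphosphate, at 1.74-fold (adjusted p = 0.00644) and DHCR7, the last enzyme of the pathway, at 1.43-fold (adjusted p = 0.0168). Glycolysis and hypoxia genes had a median of 0.16 (adjusted p = 0.0419; adjusted p = 0.872 with an estimated correlation), with the aldolases ALDOC at 1.59-fold and ALDOA at 1.28-fold and the isomerase GPI at 1.33-fold. Amino acid and ER stress genes had a median of 0.17 (adjusted p = 0.0448; adjusted p = 0.872 with an estimated correlation), with PPP1R15A, a regulatory subunit that reverses eIF2 phosphorylation, at 1.43-fold. On Jak2-9 replicate 1 the median deviation from the other 2 Jak2-9 arrays was 0.22 for amino acid and ER stress, the highest of the 20 lists, 0.15 for cholesterol synthesis and 0.04 for glycolysis and hypoxia. Without that array camera at its preset correlation still called cholesterol synthesis (adjusted p = 0.00359) and glycolysis and hypoxia (7.26e-05). It lost amino acid and ER stress (0.0563) and called JAK-STAT targets and ERK output (0.0360 each). Fry called no list without that array. Its adjusted p was 0.196 for cholesterol synthesis and 0.185 each for glycolysis and hypoxia and ERK output. With all arrays, 8 cholesterol synthesis, 3 glycolysis and hypoxia and 9 amino acid and ER stress members rose adjusted over the list alone. JAK-STAT targets, with a median of 0.20, were the only list called by fry (adjusted p = 0.0214; 0.162 without Jak2-9 replicate 1) but not by camera (0.0710). Among them GFI1B rose (0.41, adjusted p = 0.0208; 0.0568 without GFP replicate 1, 0.0506 without Luc replicate 1). MVD passed on leaving out each array. Without Jak2-9 replicate 1, DHCR7 (adjusted p = 0.0649), ALDOC (0.0746), GPI (0.127), PPP1R15A (0.128) and ALDOA (0.181) no longer passed. ALDOC was also lost without Luc replicate 1 (0.0503) or 2 (0.0573). PPP1R15A was lost without GFP replicates 1 (0.0634), 2 (0.0503) and 3 (0.0700), Jak2-10 replicate 1 (0.0524), Jak2-9 replicate 2 (0.0597) and Luc replicates 1 (0.0700) and 2 (0.0828). GPI was lost without GFP replicates 1 (0.0639), 2 (0.0724) and 3 (0.0700), Jak2-10 replicate 1 (0.0509) and Luc replicates 1 (0.0679), 2 (0.0750) and 3 (0.0650). ALDOA was lost without GFP replicates 1 (0.0954), 2 (0.1002) and 3 (0.0545), Jak2-10 replicates 1 (0.0636) and 2 (0.0667) and Luc replicates 1 (0.0870), 2 (0.107) and 3 (0.0698), and with quantile normalization (0.0782). The balance of directions turned on the setting. Median centring of the arrays moved the split to 756 up and 215 down. Rises also led without Jak2-9 replicate 2 (575 up, 305 down) or 3 (854 up, 455 down). Falls led without Jak2-9 replicate 1 (36 up, 120 down), without each control array, and with only the arrays compared (39 up, 118 down). They also led without Jak2-10 replicates 1 (89 up, 138 down), 2 (105 up, 150 down) and 3 (155 up, 175 down). The count was 156 without Jak2-9 replicate 1, 880 without replicate 2 and 1309 without replicate 3 of that hairpin. It was 159, 190 and 213 without GFP replicates 1, 2 and 3, 199, 157 and 215 without Luc replicates 1, 2 and 3, and 227 without Jak2-10 replicate 1.

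In the JAK-STAT component, differentiation and cell cycle lists some members passed with Jak2-9. SLC25A37 fell (-0.64, adjusted p = 0.00256) and the JAK-STAT component IFNAR2 rose (0.40, adjusted p = 0.00925), and both passed on leaving out each array. The rise of IFNAR2 was read at its brightest probe set. In knockdown versus control the mean of its probe sets gave 0.08 (limma, adjusted p = 0.497). The globins HBB (0.42) and HBZ (0.62), SELP (0.43) and CD9 (0.42), the replication gene MCM2 (0.39) and the mitotic kinases AURKB (0.47) and PLK1 (0.45) also passed, but these calls depended on single arrays: without Jak2-9 replicate 1 their adjusted p-values were 0.150, 0.120, 0.0791, 0.0688, 0.162, 0.143 and 0.136, and leaving out 7, 10, 5, 4, 9, 7 and 10 of the 12 arrays in turn ended the calls. Adjusted over the list alone, 8 erythroid, 3 megakaryocyte, 1 G1/S and 4 G2/M genes rose, and 2 erythroid genes fell.

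Jak2-10 changed 82 genes, 77 down and 5 up; array weights gave 145 down and 48 up, and a fit of only the arrays compared 117 down and 15 up. The 5 were ZNF236 (1.58 ± 0.32, SE), PTN (0.75 ± 0.13), GALK1 (0.58 ± 0.12), B3GALT4 (0.41 ± 0.08) and TECPR2 (0.41 ± 0.09), named after their values were seen. With this hairpin POLQ was at -2.40 and LINC00680 at -1.98 on the log2 scale, against -2.49 and -2.92 with Jak2-9. No list was called for Jak2-10. The count was 39 and 38 without GFP replicates 1 and 2, 40, 53 and 38 without Luc replicates 1, 2 and 3, 26, 30 and 26 without Jak2-10 replicates 1, 2 and 3, and 149 without Jak2-9 replicate 1.

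Both hairpins moved many genes alike. Across genes, which are not independent replicates, their log2 fold changes correlated with r = 0.641 (Spearman rho 0.483) against shared controls. Unchanged hairpins simulated against the same controls gave a mean r of 0.333 and a mean rho of 0.315. With the controls split, r was 0.497 (Jak2-9 against GFP, Jak2-10 against Luc) and 0.506 (the reverse). The covariance was 0.0215, against 0.00450 in the simulation, a difference of 0.0170. In all, 70 genes fell and 3 rose with both hairpins, against 1.14 and 0.0800 for independent lists. The lists share control arrays and 1 estimate of the spread per gene, so they cannot be independent and that baseline is too low. With split controls 52 fell and 2 rose (0.509 and 0.00553 for independent lists), and 16 fell and 0 rose in the reverse split (0.196 and 0). The estimate of the spread is still shared there. Simulated unchanged groups shared 0 calls (limma) in 20 runs, a result nearly fixed by noise that was independent between genes and arrays. The simulations held no variation shared by the arrays of a reagent.

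No single gene differed between Jak2-10 and Jak2-9 (limma, 0 genes, lowest adjusted p = 0.499; 1174 at unadjusted p under 0.05, 875 lower in Jak2-10, and 0 with array weights). As lists, camera placed JAK-STAT target genes (median -0.16), amino acid and ER stress genes (-0.12) and glycolysis and hypoxia genes (-0.13) lower with Jak2-10 (adjusted p = 0.0401 for each), and all 3 calls were lost with an estimated correlation (adjusted p = 0.806 with an estimated correlation). Members with the lowest p were FOS (-0.32 ± 0.10, SE) and SOCS3 (-0.25 ± 0.10), PHGDH (-0.42 ± 0.15) and TRIB3 (-0.42 ± 0.15), and GPI (-0.31 ± 0.11) and HK1 (-0.28 ± 0.11), each with adjusted p = 0.499. No member of the 3 lists passed adjusted over the list alone. Without Jak2-10 replicate 3 or Jak2-9 replicate 2, 0 lists were called: JAK-STAT targets had adjusted p = 0.297 and 0.191, amino acid and ER stress 0.356 and 0.191, and glycolysis and hypoxia 0.356 and 0.540. JAK-STAT targets were also lost without Jak2-9 replicate 3 (0.114), and amino acid and ER stress without Jak2-9 replicate 1 (0.0878).

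Both controls were compared as background. Luc and GFP differed in 0 genes (limma, lowest adjusted p = 0.245; 229 at unadjusted p under 0.05, and 2 with array weights). Cholesterol synthesis was higher in Luc as a list (median 0.07, camera adjusted p = 0.0165), a call lost with an estimated correlation (adjusted p = 0.945 with an estimated correlation); LSS (0.24 ± 0.12, SE) and HSD17B7 (0.22 ± 0.11) had the lowest p, neither past the threshold nor adjusted over the list alone. The list was not called without GFP replicate 3 (adjusted p = 0.208), Luc replicate 2 (0.529) or Luc replicate 3 (0.222), and 2 lists were called without GFP replicate 2 or Jak2-10 replicate 3. The 166 genes that fell with JAK2 knockdown had a median of 0.17 in Luc minus GFP, and 87.3% were higher in Luc, against 44.8% of all genes. The Alu probe set was 14.66 ± 0.02 in Luc and 14.56 ± 0.08 in GFP (SD, n = 3; exact two-sided permutation p = 0.200, where 0.1 is the smallest possible).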

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

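For Jak2-9 replicate 1 the long-gene test and the 3' minus 5' comparison were chosen after the result was seen, while the test against the Jak2-10 effect and the counts of splits were written beforehand. The hairpins were compared directly, which called 3 gene lists: JAK-STAT target genes (median log2 difference -0.16), amino acid and ER stress response (-0.12) and glycolysis and hypoxia response (-0.13), all lower with Jak2-10 by camera at its preset correlation. The calls were lost with an estimated correlation (adjusted p = 0.806 with an estimated correlation for each) and with fry (0.101, 0.298 and 0.298). Arrays of 3 against 3 make 10 splits, too few for a share under 0.05; 2 splits gave 3 or more lists, with 3 lists in the real split and 3 in the highest other. For single genes all 10 splits gave at least the real 0, with 1 in the highest other.

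A signal outside the gene measurements was the bacterial spike-in control (bioB and bioC), which averaged 9.85 on the log2 scale on Jak2-10 replicate 3, against 8.56 to 9.00 on the control arrays. No other knockdown array passed that range by its own width.

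Jak2-9 replicate 1 deviated from the other Jak2-9 arrays in 253 genes by more than 2-fold. A bias against long genes is a candidate explanation. Across 11873 genes with a genomic span, its deviation had a rank correlation of -0.305 with the span, against -0.07 to 0.07 on the 9 arrays of other groups, with median deviations of 0.19 in the shortest 25% of genes and -0.06 in the longest. A stronger JAK2 knockdown stays open: JAK2 lay 0.62 lower on this array than on its 2 mates, and its deviation correlated with the Jak2-10 effect at r = 0.242, between the limits of 0.1 and 0.3 set beforehand. Lower RNA quality also stays open, since the 3' minus 5' difference of ACTB and GAPDH on this array was the highest of the 12, 0.26 against 0.04 and 0.06 on its 2 mates.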

How the results depend on the processing

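In knockdown versus control the direction of JAK2 (-0.74 to -0.56 leaving out each array, adjusted p 0.000624 to 0.0201; -0.52 without the 2 doubtful arrays) and its side of the threshold held with median centring, quantile normalization, without the dimmest 30%, with the mean of its probe sets, without hairpin terms, with the hairpin as a random block and without each array. The 12 genes named for falling in all 4 comparisons kept adjusted p under 0.05 (knockdown versus control) in those settings and with array weights. The size of the fall did not hold for all, and for SLC35E1 it was -0.27 with the mean of all probe sets. For LINC00680, POLQ, CTTNBP2NL, GABBR1, ANKRD36B, SNHG3 and ZNF721 that mean equalled the value at the brightest probe set. The setting could thus not test these genes. No single named gene changed direction under the settings applied to it. Counts of genes and lists carry no sign, so a reversal could not be seen in them. The balance of directions with Jak2-9 did turn over. It was 191 up and 176 down in the main fit and 36 up and 120 down without Jak2-9 replicate 1. With only the arrays compared it was 39 up and 118 down. Leaving out each array in turn gave 131 to 352 genes for knockdown versus control, 1 to 38 in all 4 comparisons, 156 to 1309 for Jak2-9, 26 to 149 for Jak2-10, 0 to 1 for Luc versus GFP and 0 for Jak2-10 versus Jak2-9. It gave 0 to 3 lists for knockdown versus control, 0 to 4 for Jak2-10 versus Jak2-9, 0 to 2 for Luc versus GFP, and r from 0.572 to 0.688. Array weights gave 540 genes (269 up, 271 down) in knockdown versus control, 63 in all 4 (6 up), 193 for Jak2-10 (48 up) and 2 for Luc versus GFP. A minimum of 2-fold left 24, 7, 43 (Jak2-9) and 15 (Jak2-10) by construction; single probe sets gave 704, 69, 956 and 308. Median centring gave 971 genes for Jak2-9 and 285 (135 up, 150 down) in knockdown versus control, so that there, as with array weights, the excess of falls was nearly gone. GFP alone as control gave 41 genes and 2 lists, and Luc alone 118 genes, with fewer arrays. Only the arrays compared gave 157 genes for Jak2-9 and 132 for Jak2-10; for knockdown versus control that setting is the same fit. Leaving out the 2 doubtful arrays, chosen after seeing the data, gave 208 genes for Jak2-9, 19 in all 4 (2 up) and 3, 0 and 2 lists for knockdown versus control, Jak2-10 versus Jak2-9 and Luc versus GFP. The mean of all probe sets gave 1, 0 and 2 lists, and leaving out the dimmest 30% gave 0 for Jak2-10 versus Jak2-9. Camera with an estimated correlation and fry each gave 0 lists for Jak2-10 versus Jak2-9 and 0 for Luc versus GFP. Split controls gave r of 0.497 and 0.506. Among single named genes and lists, 24 values lost and 9 gained the threshold under other settings, and 40 and 4 on leaving out an array. The cause was not tested where none is stated.

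The replicate numbers showed no clear pairing of the arrays. Same-numbered arrays correlated from -0.12 to 0.18, against -0.20 to 0.17 for other numbers. Of the same-numbered pairs 5 of 18 were over 0.1, and 5 of 12 arrays were best matched by their own number. A weak pairing is not excluded. With a replicate block, 47 genes (1 up) were called for Jak2-10, 545 for Jak2-9, 222 in knockdown versus control and 12 in all 4 comparisons. GFI1B passed in knockdown versus control (adjusted p = 0.0496), and ALDOA no longer did with Jak2-9 (0.0505). Signal over background limits dim probe sets, for which detection calls were not used here.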

Other observations

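Tests of gene families other than core spliceosome and ribosomal proteins, of the fallen genes, and of intervals of JAK-STAT targets were chosen after the results were seen; the counts of splits and the test of dim targets were not. The 228 measured ZNF zinc finger genes held 13 that fell and 2 that rose in knockdown versus control. ZNF160 (-1.08), ZNF721 (-1.02) and ZNF331 (-0.92) fell most. The family was picked because members had been seen among the fallen genes, so its test adds no evidence (camera p = 0.0185 with an estimated correlation, 1 of 5 families and not adjusted; p = 0.0540 for Jak2-10). Of 11 SRSF splicing factor genes 2 fell and 10 lay below 0, but the list was not called (camera p = 0.126 with an estimated correlation), nor were 27 RBM RNA-binding motif genes, 3 of which fell (p = 0.286). For 41 core spliceosome proteins (1 rose) p was 0.656, and for 40 cytosolic ribosomal proteins (0 past the threshold by limma) it was 0.867, with medians of 0.07 and 0.01.

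Splits of the arrays into other groups tested whether chance gives the counts. Of 100 splits of 6 against 6 arrays, 1, the real one, gave 218 changed genes, and the highest other gave 47. Likewise 1 of 100 gave 15 genes in all 4 comparisons, with 0 in the highest other. For Jak2-9 (367 genes) and Jak2-10 (82 genes), 1 of 84 splits each, the real one, was as large, and the highest other gave 0. Chance in how single arrays fell into the groups is thus an unlikely source of these 4 counts. It is not excluded, since arrays of 1 reagent may not be independent. Mixed splits also put arrays of both arms into 1 group, which widens the spread within groups and lowers their counts. For lists in knockdown versus control, all 100 splits gave at least the real 0, with 5 in the highest other. Between Luc and GFP all 10 splits gave at least 0 genes (highest other 0), and 4 gave at least the real 1 list (highest other 2); 10 splits are too few for a share under 0.05. Between reagents chance is left open: the 4 reagents pair in only 3 ways, of which the real one gave 218 genes and the other 2 gave 0 each.

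For the genes that fell with both JAK2 hairpins, RNA degradation strong enough to show in ACTB and GAPDH is argued against. Their 3' minus 5' difference differed by -0.0284 between arms (95% interval -0.12 to 0.07). These 2 transcripts cannot exclude degradation limited to others. A single distant array is argued against, since 166 of 166 fallen genes were still called without Jak2-9 replicate 1. Less Alu-containing RNA or DNA in the knockdown samples, such as unspliced transcripts, may contribute: the Alu probe set differed by -0.55 between arms. Of probe sets with no single gene name 4.88% fell, against 1.52% of the brightest of each gene (Fisher's exact p = 2.28e-24, with probe sets not independent). Other probe sets of named genes also fell more often, 3.16% (Fisher's exact p = 5.84e-14), so the excess is not particular to unnamed probe sets. Both classes were dimmer than the brightest ones (median log2 4.74 and 5.17 against 6.28). Whether the fallen probe sets lie in introns or Alu repeats was not tested. Loss of JAK2 alone, the biological explanation in the design, stays open. The controls had like JAK2 levels, yet the fallen genes had a median of 0.17 in Luc minus GFP. By camera, which sets a list against all other genes, p was 0.0148 with an estimated correlation, and by limma's fry p was 0.0623. Only fry sets the list against the spread between arrays, so a shift beyond that spread was not shown for the fallen genes. The 15 genes called in all 4 comparisons passed by both (median 0.30, camera p = 0.00166 with an estimated correlation, limma's fry p = 0.00554). Both sets were selected on arrays that include these controls. Between hairpins the fallen genes were higher with Jak2-10 (median 0.16, camera p = 0.0597 with an estimated correlation; 0.0411 for the 15 genes), but this gives no order by JAK2 level, since without Jak2-9 replicate 1 JAK2 was lower with Jak2-10 by -0.03 and the median was 0.06 (p = 0.150; 0.0609 for the 15 genes).

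JAK-STAT target genes did not fall although JAK2 did. Noise that hides a fall as large as the JAK2 estimate is argued against: for 22 of 22 targets the 95% interval excluded a log2 change of -0.67. The lowest bound was -0.52 (CCND2), or 69.6% of control, which lies within the interval of JAK2 itself (53.5% to 74.3%). Falls smaller than that of JAK2 are not excluded. Signals too dim to fall stay open for the 4 targets among the dimmest 30% of genes, for which the intervals cannot settle the question. Whether the JAK2 kinase left in these cells could suffice for target expression was not tested, since protein and phosphorylation were not analysed here.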
